A study of Mus musculus with 7 samples.

How the data were processed

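RNA was measured in invariant natural killer T (iNKT) cells, T cells that carry a semi-invariant receptor for lipids presented by CD1d, sorted from the colon of C57BL/6 mice kept free of specific pathogens. Per the labels, 300 to 3000 sorted cells went into each library, which was made with a full-length, low-input cDNA kit and read as single ends of 50 bp. The labels give 3 libraries at 14 days of age and 4 at 56 days, and each was mapped to its age by its own label. Nothing in the labels says whether libraries come from separate animals or pools, so p-values measure only the spread between these libraries, which may be in part technical.

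The authors deposited 1 table of TPM, a transcript share normalised for gene length and library total, for 25267 gene symbols, and each library sums to the same total. STAR, HTSeq, Partek 10 and DESeq2 and the builds GRCm38 and mm10 are named per the submitters' processing notes, with no role or order. The annotation and the step that made the TPM values are not given in the sources used here. Of the symbols, 24418 matched a gene name in GENCODE M21 on GRCm38, from which coordinates of a few genes were taken. T cell receptor and immunoglobulin constant genes were not analysed here.

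The low TPM values fall on steps. For 17147 of the 17147 genes above 0 in at least 2 libraries, the values of all libraries were whole multiples of 1 read within 0.001 reads. For a gene seen in few libraries such a match is easy to reach, so it decides little there. Of the 11732 genes above 0 in all libraries, 11732 matched. On 4000 simulated genes the same procedure returned 99.0% of genes exactly. The recovered totals were 19092976, 23066917 and 26979710 reads for day 14 replicates 1 to 3, and 23127926, 22774048, 29015101 and 22783639 for day 56 replicates 1 to 4. These reads were used only to describe depth, for thinning and for an added alternative, and the procedure can be out by a common factor for a gene seen in few libraries.

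The main test was limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with a trend) on log2(TPM + 1) with age as the term, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Genes with a TPM of at least 1 in at least 3 libraries were tested, which left 12544. Fold changes are day 56 minus day 14 on the log2(TPM + 1) scale, which understates the change of low genes. Gene lists were tested with limma's camera at its preset correlation of 0.01, adjusted over the 43 of 45 lists with at least 5 tested members. Camera with an estimated correlation, limma's fry, and a two-sided exact permutation test of each list's mean over the 35 splits of the 7 libraries were run beside it. The smallest p that the exact test can give is 0.0286, so that at least 25 of the 43 lists would have to reach it for any to pass after adjustment. Members of a list were also adjusted over the list alone.

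The lists, tests, alternatives and the rule for named genes were set before the data were examined. The rule takes up to 12 genes each way with adjusted p under 0.05, no overlap between ages and a mean of at least 10 TPM, which gave 0 genes. It also takes the members of each described list past the threshold, or else up to 2 members with the highest mean TPM, and 30 genes named in advance, of which 1 is not reported here. The members past the threshold when adjusted over the list alone, and the 10 genes each way with the smallest p among genes without overlap, were added after the values were seen. Alternatives covered the pseudocount, the filter, scaling, the empirical Bayes settings, library weights, a replicate block, the number of genes detected, leaving out each library, and the list tests. Limma's voom on recovered reads, a T cell covariate, and leaving out both day 56 libraries rich in epithelial transcripts were added after seeing the data. Robust empirical Bayes acts on the gene test alone, so it repeats the main list results by construction. The replicate block leaves day 56 replicate 4 without influence, as no other library has that number.

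The gene test was tested on simulated data with the real means and spreads, 12544 genes and independent noise. For the comparison of day 56 with day 14 it called 1 of 50 genes changed by 1 on the log2 scale, 9 of 50 changed by 2, 22 of 50 changed by 3 and 31 of 50 changed by 4, and 1 unchanged gene. With no age effect, camera at the preset correlation called 0.3 of 43 lists on average over 20 simulations with independent genes. When the members of each list shared a random shift per library of 1 SD, it called 21.1 on average, against 0.1 with an estimated correlation. Figures were drawn with matplotlib 3.10.9. No pair of libraries shared an identical value above 0, so none was counted as a duplicate.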

Results

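Transcript levels of colonic iNKT cells were compared between 14-day-old and 56-day-old mice, with 3 libraries at day 14 and 4 at day 56. The series concerns how macrophages of embryonic origin set the number of iNKT cells at barrier surfaces in early life, and this comparison asks how the cells' transcripts differ between early life and adulthood. Between 10577 and 13052 genes reached a TPM of at least 1 per library, and the recovered depth was 19092976 to 29015101 reads per library.

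The libraries differed widely in T cell transcripts within each age. Cd3e, a subunit of the T cell receptor complex, stood at 968, 524 and 226 TPM in day 14 replicates 1 to 3 and at 553, 653, 23.8 and 1071 TPM in day 56 replicates 1 to 4. Epcam, an epithelial adhesion molecule, stood at 1020 TPM in day 56 replicate 3 and 320 TPM in day 56 replicate 1, against 2.99 to 69.2 TPM in the other 5 libraries. The mean log2(TPM + 1) of the iNKT and T cell identity list was 2.51 in day 56 replicate 3 and 5.08 to 7.09 elsewhere. The first principal component of the 1000 most variable genes held 53.4% of the variance and placed libraries of both ages at each end, with day 56 replicate 4 at -68.3 and day 56 replicate 3 at 80.5. The median Pearson correlation was 0.839 over the 12 pairs of libraries of different ages, 0.886 over the 3 pairs within day 14 and 0.772 over the 6 pairs within day 56.

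**Figure D1:**
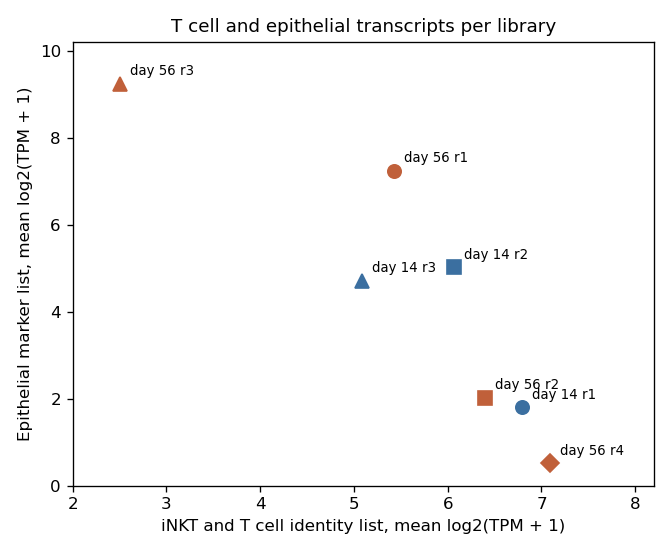
Mean log2(TPM + 1) of the iNKT and T cell identity list (horizontal axis) and of the epithelial marker list (vertical axis), 1 point per library, blue for day 14 and orange for day 56, with the marker shape giving the replicate number (r). Day 56 replicate 3 has the lowest T cell mean, 2.51, and the highest epithelial mean, 9.24.

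No single gene passed the test over all genes. With limma, 0 genes were higher and 0 lower at day 56 at an adjusted p under 0.05, and the smallest adjusted p was 0.436. At an unadjusted p under 0.05 there were 646 genes, 100 higher and 546 lower, where 627 are expected by chance. Limma's voom on recovered reads also called 0 genes, with 572 at an unadjusted p under 0.05. Array quality weights called 313 genes higher and 1239 lower, but their estimate did not converge. The replicate block and the fit without day 56 replicate 4 each called only Jchain, with the same log2 change of 11.4. They are not separate checks, since only day 56 has a replicate 4 and the block fits that library exactly. All day 56 libraries lay above all day 14 libraries for 150 genes and below them for 857, together 8.03% of genes where chance gives 5.71%. The median log2 change over all tested genes was -0.25 and became -0.00309 with median-of-ratios scaling. Camera compares members with the other genes, while fry and the exact test use the members alone and so include such an overall shift.

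Transcripts of dividing cells were lower at day 56, though camera with an estimated correlation called neither of their lists (adjusted p = 0.157 for both). Top2a, the topoisomerase that untangles chromosomes before division (GRCm38, chromosome 11, 98992943 to 99024189), stood at 62.1 ± 15.6 TPM at day 14 (SD, n = 3) and 15.3 ± 5.72 TPM at day 56 (SD, n = 4). Ube2c, a ubiquitin-conjugating enzyme of mitotic exit, stood at 337 ± 68.0 and 93.5 ± 51.2 TPM, and Mki67, a marker of cycling cells, at 8.03 ± 2.03 and 2.22 ± 1.45 TPM. The G2/M and mitosis list had a mean log2 change of -1.41 over 40 members, of which 27 had every day 56 library below every day 14 library. The DNA replication and S phase list had a mean of -1.21 over 35 members, 18 of them without overlap.

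Adjusted over the list alone, 24 of the 40 G2/M members fell and 0 rose, and 12 of the 35 S phase members fell and 0 rose, against 0 of either list over all genes tested. Those that fell included Tacc3 (log2 change -2.02, SE 0.40), Kif20a (-2.16, SE 0.47), Rrm2, a subunit of ribonucleotide reductase (-2.09, SE 0.49), Uhrf1 (-1.92, SE 0.43) and the replicative helicase subunit Mcm5 (-1.45, SE 0.41). Pcna, the replication clamp, stood at 190 ± 40.7 and 134 ± 51.2 TPM and did not pass, nor did Fen1 or Hmgb2. Camera gave an adjusted p of 6.9e-24 for G2/M and 1.97e-18 for S phase at the preset correlation, and an adjusted p = 0.157 for both with an estimated correlation. Fry gave adjusted p values of 0.0225 and 0.0277 (limma). The exact permutation p was 0.0286 for each, the smallest possible, and 0.307 after adjustment over the 43 lists.

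Genes of MHC class II antigen presentation were higher at day 56, though camera with an estimated correlation did not call their list (adjusted p = 0.0844). Cd74, the invariant chain (GRCm38, chromosome 18, 60803848 to 60812652), stood at 796 ± 201 TPM at day 14 (SD, n = 3) and 1768 ± 139 TPM at day 56 (SD, n = 4), and H2-Ab1, a class II chain, at 530 ± 229 and 1254 ± 104 TPM. The list's mean log2 change was 0.79 over 10 members. Adjusted over the list alone, 5 members rose, namely Cd74, H2-Aa, H2-Ab1, H2-Eb1 and H2-DMb1, against 0 over all genes tested. Camera gave an adjusted p of 2.35e-10 at the preset correlation and an adjusted p = 0.0844 with an estimated correlation, and fry an adjusted p of 0.0225 (limma). The exact permutation p was 0.0286, or 0.307 after adjustment over the lists.

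**Figure D2:**
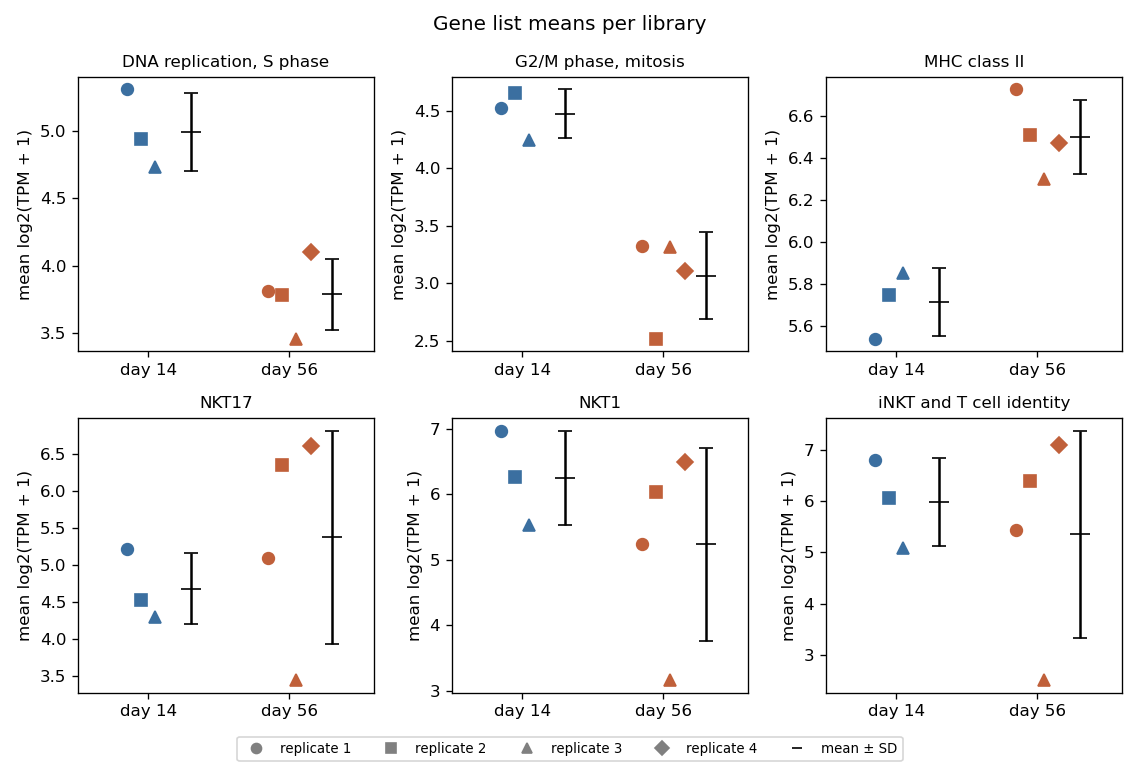
Mean log2(TPM + 1) of 6 gene lists, 1 point per library with the marker shape giving the replicate number, and the mean ± SD of each age in black; each panel has its own vertical scale, which does not start at 0. The ages do not overlap for the S phase, G2/M and MHC class II lists and overlap for the NKT17, NKT1 and identity lists, where day 56 replicate 3 is lowest.

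Genes of the subsets of iNKT cells were compared through 3 lists. The chemokine receptor Cxcr6 stood at 910 ± 614 TPM at day 14 (SD, n = 3) and 2423 ± 2100 TPM at day 56 (SD, n = 4), and Tmem176a at 311 ± 145 and 1002 ± 595 TPM; neither passed. The NKT17 list had a mean log2 change of 0.69 over 22 members, 18 of them higher and 4 lower at day 56. Of its members 1, Serpinb1a (1.83, SE 0.34), rose when adjusted over the list alone. Camera gave an adjusted p of 3.1e-08, and an adjusted p = 0.668 with an estimated correlation; the exact permutation p was 0.4. The list's mean per library followed T cell content, at 3.45 in day 56 replicate 3 and 5.10 to 6.61 in the other day 56 libraries. Its mean log2 change was 1.34 without day 56 replicate 3, 0.37 without day 56 replicate 2 and 0.28 without day 56 replicate 4, and its call held in each.

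Among NKT1 genes, which serve interferon and cytotoxic responses, Gzma, a granzyme (GRCm38, chromosome 13, 113093825 to 113100981), stood at 53.6 ± 25.5 TPM at day 14 and 4.996 ± 2.68 TPM at day 56, a log2 change of -3.17 (SE 0.56), and fell when adjusted over the list alone. Ifng, the gene of interferon gamma (GRCm38, chromosome 10, 118441046 to 118445892), stood at 554 ± 437 and 110 ± 103 TPM, Gzmb at 1517 ± 795 and 564 ± 421 TPM, Nkg7 at 3312 ± 1683 and 1745 ± 1136 TPM, and Tbx21, which encodes T-bet, at 64.7 ± 37.6 and 36.8 ± 42.9 TPM; none of these passed. The NKT1 list had a mean of -1.02 over 27 members, with a camera adjusted p of 0.0396 at the preset correlation and an adjusted p = 0.987 with an estimated correlation. The call held in 13 of the 23 alternatives. It ended without day 14 replicate 1 (mean -0.67, camera adjusted p 0.937), day 56 replicate 1 (mean -1.03, adjusted p 0.0641) or day 56 replicate 3 (mean -0.33, adjusted p 0.658). The identity list (mean -0.62) and the NKT2 list (mean -0.43) did not pass, and the NKT2 member Ccr8 stood at 387 ± 216 and 864 ± 571 TPM.

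Other lists that were lower passed camera only at the preset correlation. Cytotoxic effectors (mean -1.02, adjusted p = 0.839 with an estimated correlation) and NK receptors (mean -0.78, adjusted p = 0.987 with an estimated correlation) were lower, and Fcer1g and Klra5 fell when adjusted over the NK receptor list alone. Without day 14 replicate 1 the calls ended for cytotoxic effectors (mean -0.80, adjusted p 0.314, limma), NK receptors (mean -0.52, adjusted p 0.656) and ribosome biogenesis and MYC targets (mean -0.41, adjusted p 0.375). Without day 56 replicate 3, the library with the most epithelial transcripts, they ended for the same lists at means of -0.52, -0.25 and -0.51 (adjusted p 0.449, 0.792 and 0.0581, limma). The call for cytotoxic effectors also ended without day 56 replicate 1 (mean -0.95, adjusted p 0.0767, limma). Over all libraries ribosome biogenesis and MYC targets had a mean of -0.55 (adjusted p = 0.691 with an estimated correlation).

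The early T cell and fetal growth list was lower (mean -1.13, adjusted p = 0.668 with an estimated correlation), and 3 members fell when adjusted over the list alone: Cdkn1c, an imprinted cell cycle inhibitor, Dlk1 and Igf2bp3. Its mean log2(TPM + 1) was 2.69, 4.44 and 4.62 in day 14 replicates 1 to 3 and 3.56, 2.85, 2.68 and 2.05 in day 56 replicates 1 to 4. The stromal and endothelial markers stood at 5.03, 7.58 and 7.79 and at 6.62, 5.90, 6.21 and 4.59 in the same libraries. Those markers were lower at day 56 (mean -0.97, adjusted p = 0.987 with an estimated correlation). Without day 56 replicate 4 the calls ended for the early list (mean -0.89, adjusted p 0.0671, limma) and the stromal list (mean -0.55, adjusted p 0.342). Without day 14 replicate 1 the means were -1.75 and -1.85. The stromal call also ended without day 14 replicate 2 (mean -0.58, adjusted p 0.433, limma), without day 14 replicate 3 (mean -0.47, adjusted p 0.480). It ended, too, with the replicate block (mean -0.55, adjusted p 0.382, limma). The block rests on the same libraries as the fit without day 56 replicate 4 and repeats its means. The number of genes detected as a covariate also ended the stromal call (mean -0.47, adjusted p 0.365, limma). The early list's call ended with the block (mean -0.89, adjusted p 0.0944, limma) and with a filter of at least 5 TPM (mean -1.32, adjusted p 0.149).

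Epithelial markers (mean 0.91, adjusted p = 0.987 with an estimated correlation), oxidative phosphorylation (mean 0.29, adjusted p = 0.870 with an estimated correlation) and cholesterol synthesis (mean 0.20, adjusted p = 0.668 with an estimated correlation) were higher. The epithelial call ended without day 56 replicate 3 (mean -0.59, adjusted p 0.503, limma), day 14 replicate 1 (mean -0.11, adjusted p 0.103) or day 56 replicate 1 (mean 0.082, adjusted p 0.205). The mean was 1.5, 1.82 and 2.32 without day 14 replicate 2, day 56 replicate 2 and day 56 replicate 4. Oxidative phosphorylation lost its call without day 56 replicate 3 (mean -0.045, adjusted p 0.197, limma), and its mean was 0.45 without day 56 replicate 2 and 0.45 without day 56 replicate 4. The mean for cholesterol synthesis was 0.00061 without day 56 replicate 3 (adjusted p 0.0496, limma), 0.030 without day 14 replicate 1 (adjusted p 0.0305), 0.41 without day 14 replicate 3 and 0.32 without day 56 replicate 1. Its call ended without both libraries rich in epithelial transcripts (mean 0.083, adjusted p 0.0546, limma).

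Heat shock genes had a mean of 0.18 and a median of -0.04, with an adjusted p = 0.363 with an estimated correlation, and Hspa1b rose when adjusted over the list alone. The call held in 13 of the 23 alternatives. It ended without day 14 replicate 1 (mean 0.045, adjusted p 0.160, limma), day 14 replicate 3 (mean 0.26, adjusted p 0.0709), day 56 replicate 1 (mean 0.10, adjusted p 0.109) and day 56 replicate 2 (mean 0.074, adjusted p 0.187). Without day 56 replicate 4 the mean was 0.36. It also ended with a pseudocount of 5 (adjusted p 0.0542, limma), no filter (adjusted p 0.0606), quantile normalization (adjusted p 0.397) and the number of genes detected as a covariate (adjusted p 0.115).

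Among B and plasma cell markers, Jchain, the joining chain of secreted IgA and IgM (GRCm38, chromosome 5, 88519809 to 88527891), stood at 0, 0 and 1.28 TPM in day 14 replicates 1 to 3 and at 1645, 7948, 3440 and 89.2 TPM in day 56 replicates 1 to 4. Jchain and Tnfrsf17, a receptor of plasma cells, rose when adjusted over the list alone. The list had a mean of 1.27 and a median of 0.09 over 10 members, a camera adjusted p of 0.0245, and an adjusted p = 0.363 with an estimated correlation. The call held in 12 of the 23 alternatives. It ended without day 14 replicate 3 (mean 1.18, adjusted p 0.119, limma) or day 56 replicate 1 (mean 1.27, adjusted p 0.0980), with voom (mean 1.76, adjusted p 0.249) and without both libraries rich in epithelial transcripts (mean 1.19, adjusted p 0.150). It also ended with no filter (adjusted p 0.390, limma), a filter of at least 5 TPM (0.0664), median-of-ratios scaling (0.0863), array weights (0.104), the number of genes detected (0.201) and fry (0.201).

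In total 7 lists were higher and 8 lower at the preset correlation, and 0 and 0 with an estimated correlation. Of the 35 splits of the 7 libraries into 3 and 4, 21 gave at least as many lists as the 15 of the real ages, so the number of lists does not exceed what other splits of the same libraries give.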

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

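The tests of innate lymphoid, B, epithelial and plasma cells, the depth covariate and the split count for genes were chosen after related results were seen, and the T cell covariate itself was chosen after seeing the data. Of 130 list means and named genes examined among the 4 day 56 libraries, 7 had a library far from the other 3, or 5.38%, where chance flags about 5%. Day 56 replicate 3, the library with the fewest T cell transcripts, was lowest for Nkg7 at 6.84, Ccr8 at 5.45 and Il4 at 1.93 on the log2(TPM + 1) scale. Day 56 replicate 4 was highest for Fcer1g at 6.85 and lowest for Cdkn1c at 5.68 and Egr2 at 4.77. Day 56 replicate 1 alone was above 0 for Dlk1, at 0.90.

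Chance cannot be excluded for the number of lists: the real ages gave 15, 21 of the 35 splits gave as many, and the highest other split gave 29. For genes the real ages gave 0, so that 35 of the 35 splits gave as many by construction and the count decides nothing; the highest other split gave 3. A split with 29 lists set day 14 replicate 3 and day 56 replicates 1 and 3 against the rest, which points to a structure of the libraries other than age.

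The cell cycle lists were lower at day 56 at the preset correlation (adjusted p = 0.157 for both with an estimated correlation), where the 2 ages are the biological difference of the design and remain untested as a cause. With the T cell identity mean as a covariate, the pooled list mean still differed by -1.30 (SE 0.18), against -1.32 (SE 0.17) without it. The covariate moved the epithelial list from 0.91 to -0.24. The bound set beforehand was met, which argues against T cell content alone as the whole source. It cannot decide about other cells that divided more at day 14, since the covariate follows only T cell content. With the identity mean subtracted, the pooled list mean differed by -0.69 (SE 1.24), within 2 SE of 0, so the reading depends on the form. That form was chosen later and adds the identity list's own spread (day 56 SD 2.02). With subtraction and without both day 56 libraries rich in epithelial transcripts, the pooled list mean differed by -2.14 (SE 0.49). With log2 recovered reads as a covariate, which moved the change of all tested genes by a median of 0.13, it differed by -1.27 (SE 0.17), which argues against a trend with depth as the whole source; thinning to the shallowest library moved that change by a median of 0.013, too little to decide although the bound set beforehand was met (-1.38, SE 0.18, on reads scaled to a common total). A change in which cells of the sort divide stays open.

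The NKT17 list was higher at day 56 at the preset correlation (adjusted p = 0.668 with an estimated correlation). With the T cell identity mean as a covariate its mean differed by 1.12 (SE 0.21), which decides nothing about cells other than T cells although the bound set beforehand was met. The list follows T cell content, which was lower at day 56 by 0.62, so the adjustment enlarges the difference from 0.69. Innate lymphoid cells, which share many of the genes and which a gate on the iNKT receptor would remove, stay open: relative to the identity list the 10 innate lymphoid markers differed by 0.60 (SE 0.59) and the NKT17 list by 1.32 (SE 0.43), and the first less 0.5 times the second was -0.058 (SE 0.39). A fit with the identity mean as a covariate, run first although the test set down was the subtraction, gave 0.32 (SE 0.15) and would have argued against them, so the reading depends on the form.

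The MHC class II list was higher at day 56 at the preset correlation (adjusted p = 0.0844 with an estimated correlation), and Jchain rose when adjusted over its list alone. The tables argue against B cells, as 11 B cell markers differed by -0.43 (SE 0.28) while the MHC class II list differed by 0.79. The tables also argue against epithelial cells. In the day 56 group, 2 libraries had an epithelial mean no higher than the highest at day 14. Their MHC class II means lay above every day 14 library, by 0.62 and 0.65, against a day 14 SD of 0.16. Macrophages, monocytes and dendritic cells were not tested as a source. Their marker list had a mean log2 change of -0.71 over 22 members, 5 higher and 17 lower. It did not pass camera at the preset correlation (adjusted p = 0.0982). Plasma cells stay open for Jchain. Of 8 other plasma cell markers, all but Eaf2 passed the filter. The mean of those that passed differed by 1.05 (SE 0.54), just within 2 SE of 0, and ranked the day 56 libraries as Jchain did. Mzb1 stood at 6.76 ± 4.66 TPM at day 14 (SD, n = 3) and 108 ± 126 TPM at day 56 (SD, n = 4).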

How the results depend on the processing

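The covariate of T cell identity, voom on recovered reads and the fit without both day 56 libraries rich in epithelial transcripts were chosen after seeing the data; the other alternatives were planned, and the planned count tests on recovered reads were not run because the deposited unit is TPM. The cause of each change below was not tested. Array quality weights called 313 genes higher and 1239 lower, from weights of 0.176 to 10.8 whose estimate did not converge. The replicate numbers do not pair the libraries (same-number correlations of deviations -0.25, -0.11 and 0.37). With the replicate block 1 gene was higher, Jchain, with 2 residual degrees of freedom, and 0 lower. The block gives the same changes as leaving out day 56 replicate 4, so these 2 alternatives are not separate checks. Leaving out single libraries gave 0 to 1 genes higher (Jchain, without day 56 replicate 4) and 0 lower, 4 to 15 lists higher and 4 to 13 lower. An estimated correlation gave 0 and 0 lists, fry 1 and 2, the number of genes detected 21 lower, the T cell covariate 11 higher, and the fit without both libraries 14 higher. The mean log2 change stayed negative for G2/M (-1.95 to -1.01) and S phase (-1.41 to -0.92) in all 23 alternatives. In all 23 it stayed positive for MHC class II (0.70 to 1.06). Each of these lists was past the threshold in 22, the exception being the estimated correlation. There the means were -1.41, -1.21 and 0.79 and the camera adjusted p values 0.157, 0.157 and 0.0844. Counts out of the 23 are not counts of independent checks, and robust empirical Bayes could not change any list. All but the estimated correlation and fry kept the preset correlation. In simulations with a shared shift and no age effect, that correlation called 21.1 lists on average. NKT17 stayed positive (0.14 to 1.80) and lost its call with the estimated correlation and with fry (0.69 in both). NKT1 lost its call with a pseudocount of 5 (-0.81), no filter (-1.02), the estimated correlation and fry (-1.02 in both), the T cell covariate (-0.56), and without day 14 replicate 1 (-0.67) or day 56 replicate 1 (-1.03). Of the 23 alternatives, the call held in 13 for NKT1 and heat shock, 12 for B and plasma cells, 15 for cytotoxic effectors, NK receptors and epithelial markers, 16 for stromal markers, 18 for the early T cell list, oxidative phosphorylation and ribosome biogenesis, 20 for cholesterol synthesis and 21 for NKT17. Directions below are relative to the other genes, so a list can turn while its mean keeps its sign. With array weights NKT1 (-0.33), T cell cytokines (0.54) and epithelial markers (-2.40) turned. With the block the identity list passed (-1.20) and the interferon list turned (-0.66). With the number of genes detected, identity (-1.57), NKT2 (-1.17), residency (-0.64) and circulation (-0.62) passed, and gut homing (-0.83) and cytokine receptors (-0.66) turned. With the T cell covariate residency turned (-0.050). Over single libraries left out, the mean ranged from -1.20 to 0.32 for identity, -1.44 to -0.33 for NKT1, -0.85 to 0.18 for NKT2, -0.48 to 0.089 for residency, -0.52 to 0.086 for circulation, -1.12 to -0.25 for NK receptors, -0.98 to 0.060 for costimulation and -1.08 to 0.071 for T cell receptor signalling, each highest without day 56 replicate 3, where all of these turned. Without both libraries rich in epithelial transcripts, identity (0.76), NKT1 (0.0091), residency (0.23), T cell cytokines (0.31), cytotoxic effectors (-0.17), NK receptors (0.031), costimulation (0.42), MHC class I (0.28), T cell receptor signalling (0.56), oxidative phosphorylation (-0.19) and epithelial markers (-2.58) turned.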

Other observations

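The genes in this paragraph are among those with the smallest p and no overlap between ages; they were chosen after their values were seen, and none passed the threshold over all genes (limma, smallest adjusted p 0.436). Values are TPM at day 14 and day 56 (SD, n = 3 and 4). H2ac8 stood at 278 ± 43.4 and 63.0 ± 21.3 TPM, H1f5 at 119 ± 9.12 and 30.9 ± 7.11 TPM, H2ac4 at 28.5 ± 9.96 and 3.83 ± 2.32 TPM, and H1f2 at 277 ± 49.2 and 1003 ± 435 TPM. All of these are histone genes. H2ac8 and H2ac4 have near-identical copies, so their levels are uncertain. Whether reads shared between related genes affect H1f5 and H1f2 was not tested. Dusp2, a phosphatase of MAP kinases, stood at 2092 ± 513 and 452 ± 213 TPM and Itm2a at 228 ± 60.1 and 43.0 ± 22.3 TPM. Lgals3, a galectin, stood at 138 ± 60.5 and 684 ± 258 TPM.

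The clock genes Nr1d1, at 63.8 ± 22.8 and 277 ± 66.7 TPM, and Dbp, at 30.5 ± 5.44 and 111 ± 27.1 TPM, were in the same selection and did not pass either. The hypothesis that the libraries were collected at another phase of the clock was tested on other genes, set before their values were seen. Of 4 genes of the opposite phase, Npas2 did not pass the filter, which left Arntl, Clock and Nfil3. The mean of 6 genes of the Nr1d1 phase less the mean of these differed by -0.082 (SE 0.25, exact permutation p = 0.829). A phase difference was not found with these genes. Nfil3 ranged from 40.3 TPM in day 56 replicate 3 to 265 TPM in day 56 replicate 4, which limits the test.

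Because T cell content varied, it was accounted for in 4 ways: not at all, as a covariate, by leaving out libraries, and by subtracting the identity mean. An earlier version of the subtraction used genes picked after their values were seen and was replaced by 23 of the genes named in advance and the 3 subset lists. Of these 26, 3 reached the smallest exact permutation p of 0.0286: Ifng (-2.32, SE 0.43), Gzmb (-1.54, SE 0.42) and the NKT17 list (1.32, SE 0.43). Cxcr6 differed by 1.34 (SE 0.42; exact permutation p = 0.0571). After Benjamini-Hochberg adjustment over the 26 the smallest value was 0.248; at least 15 would have to reach the smallest exact p for any to pass, so the adjusted values decide little.

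Each day 14 library held transcripts of both the inactive X and the Y chromosome, with Xist at 12.8, 14.1 and 9.03 TPM and Ddx3y at 18.2, 7.42 and 24.5 TPM. At day 56, replicates 1 to 4 held Xist at 1.71, 0, 25.3 and 14.5 TPM and Ddx3y at 41.1, 41.6, 0 and 0 TPM. The mix of these transcripts thus differed between libraries and in part with age, and no fit took it into account.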
